A study of Mus musculus with 9 samples.

How the data were processed

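Total RNA of mouse aorta was extracted with a mirVana kit, amplified from 0.2 µg into Cy3-labelled cRNA and hybridised to 1-colour Agilent arrays, per the labels' protocols. The authors read the images with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. The deposited scanner files give each spot's intensity on a linear scale, as processed signal, raw mean signal and local background. Per the file headers, the processed signal was background-subtracted and detrended within the array, and no scaling between arrays was applied. The authors also deposited a value table of log2 values for 91256 probes with controls. Set against the scanner values, its columns correlated with their own array at 0.9953 to 0.9999, and their medians were 4.7946 or 4.7947. The scale is log2, the values are not centred by probe and all columns share nearly the same distribution, as quantile normalization between arrays gives; the tool used for that step is not given in the sources used here. Every column of the table belongs to an analysed array, and 0 columns were left unused.

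The groups were normal diet (ND), high fat diet (HF) and high fat diet with exercise (HE), with 3 arrays each, taken from the sample titles. Slides were told apart by the array identifiers in the files. Control spots and spots with an outlier flag (17 to 29 per array) were left out, and no spot was saturated. Spots of a probe were averaged on the log2 scale. The median SD between duplicate spots of a probe was 0.088 to 0.104 on the log2 scale. The value used is log2 of the processed signal minus the array's 75th percentile of it over all probes, and a probe was kept when it was well above background on at least 3 of the 9 arrays, whatever the group. Under 50% of the probes were detected on each array. The array median, used as an alternative, therefore falls among probes not well above background, and the 75th percentile does not.

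Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0 for the robust prior) in 1 fit over all 9 arrays, with 6 residual degrees of freedom and a prior of 3.12. The 3 contrasts were HF against ND, HE against HF and HE against ND, with Benjamini-Hochberg adjustment over the 43948 probes and a threshold of 0.05. Single values were compared with two-sided exact permutation tests. Where a probe was not well above background on any array of a group, its fold is given against the lowest signal among probes well above background. Other probes can go undetected above that signal, so this is no firm bound. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for reading and for figures.

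The fit was tested on simulated data with 200 probes changed in each comparison, drawn with the means and limma's moderated spreads of the 43948 tested probes. Probes were drawn separately, without slide effects or variation that probes share, so the shares recovered may be higher than on the real arrays. Of 100 probes changed 2-fold, an adjusted p under 0.05 was reached by 55% for HF against ND, 64% for HE against HF and 61% for HE against ND. Of 100 probes changed 4-fold, it was reached by 95%, 97% and 94%. Among the unchanged probes 8, 7 and 9 were called. The search for probes with shared sequence recovered 100 of 100 planted pairs on the same strand and 100 of 100 on opposite strands. Many pairs belong to families that share a repeat, and the restriction to probes with exactly 1 partner was made after that had been seen, so values over all pairs are given beside it.

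The rule for named items, set before the data were examined, takes genes past the adjusted threshold and, where fewer than 5 pass in a direction, the 10 with the smallest unadjusted p and a difference of at least 1 on the log2 scale. The files pair no probe with a gene name, coordinate, description or transcript class, and the reference table used here holds neither probe identifiers nor sequences. Probes are therefore named by identifier, and because an identifier without a gene says little, at most 2 of the 10 per direction and comparison are printed. For the same reason the planned tests of gene lists and cell type markers, counts of long non-coding RNAs, collapsing of probes to genes, checks of sex-linked genes and adjustment for fat or muscle markers were not made. The unit tested is the probe and not the gene. Counts at an unadjusted p under 0.05 and by name series were added after no probe had passed the adjusted threshold.

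The alternatives tried were the normexp background correction with an offset of 50, quantile normalization, the array median, the 75th percentile over the 31878 probes detected on all arrays, the filter on dim probes, only the groups compared, a trended and robust prior, array weights, the replicate number or the slide as a block, the authors' value table, a criterion of unadjusted p under 0.05 with at least a 2-fold difference, and each array left out in turn. Scaling to E1A spike-in probes and the fits within a slide were added after seeing the data. Unchanged groups that share arrays were simulated 100 times for correlations and 20 times for overlaps, with each probe's own spread.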

Results

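The data describe the aorta of male C57BL/6J mice, an inbred strain that gains fat and loses insulin sensitivity on fat-rich food. Mice were kept for 12 weeks on normal diet (ND), on high fat diet (HF), or on high fat diet with exercise training in bouts labelled 60 min (HE). The study placed 8 mice in each group, 24 in all, and 3 arrays per group were analysed here. The labels do not tie an array to an animal, so p-values measure the spread between arrays. Each 1-colour array held 91188 probes of 60 bases against messenger RNAs and long non-coding RNAs, which are long transcripts without a protein product. The files pair none of these probes with a gene name, a coordinate or a transcript class, so each result is given for a probe, by its identifier and sequence. The only named mouse genes are control probes for Gapdh and Pgk1, both enzymes of glycolysis.

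Between 36.6% and 48.9% of the probes were well above background on an array. The mean share was 46.3% ± 2.68 (SD, n = 3) in ND, 44.4% ± 2.93 (SD, n = 3) in HF and 43.6% ± 6.18 (SD, n = 3) in HE. A probe entered the tests when it was well above background on at least 3 of the 9 arrays, which kept 43948 probes. Levels below are log2 values relative to the 75th percentile of the array. With 3 arrays per group, the number of replicates limits the precision of each difference.

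The arrays came from 3 slides. Slide 1 held the 3 ND arrays and HF replicate 1, slide 2 held HF replicates 2 and 3 and HE replicates 1 and 2, and slide 3 held HE replicate 3. The first principal component held 26.2% of the variance. It placed the 4 arrays of slide 1 between -42.2 and -21.4 and the 4 arrays of slide 2 between 15.5 and 72.3. HE replicate 2 lay at 72.3, and the other arrays of slide 2 lay at 31.1 or below. HE replicate 3, on slide 3, lay at -13.0. HF replicate 1 lay 12.3 units from the ND mean and 37.4 from the mean of the other HF arrays. Correlations of levels between arrays ran from 0.9567 to 0.9853, and no pair of arrays held identical values.

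**Figure D1:**
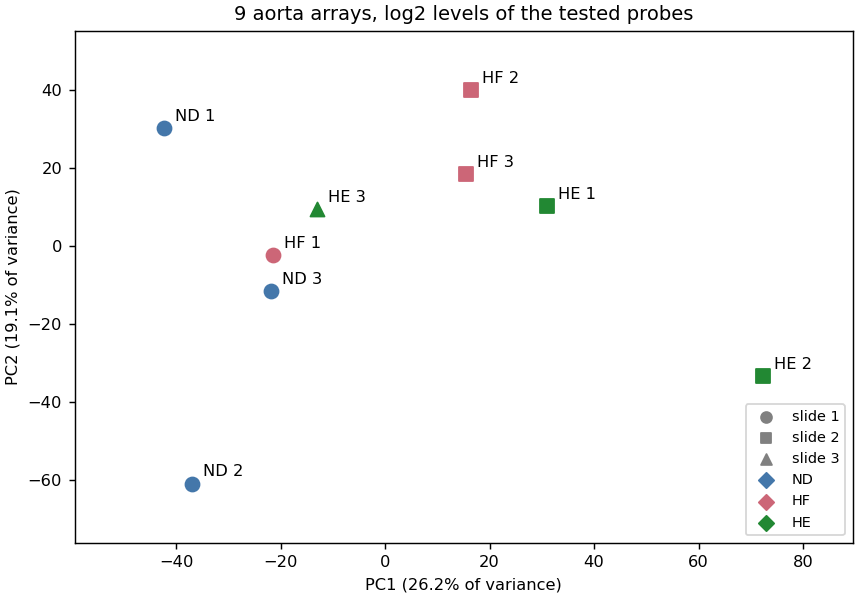
Each point is 1 array, placed by its scores on the first (x axis, 26.2% of variance) and second (y axis, 19.1%) principal components of the tested probes. Colours are groups and symbols are slides, and the 4 arrays of slide 1 lie left of the 4 arrays of slide 2. The array of slide 3, HE replicate 3, lies between them on the x axis.

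In a Gapdh and a Pgk1 probe the levels spread more between the ND arrays than the group means differed. The probe Mouse-PGK1_3 had a level of 3.30 ± 0.79 (SD, n = 3) in ND, 3.43 ± 0.33 (SD, n = 3) in HF and 3.32 ± 0.26 (SD, n = 3) in HE. The probe Mouse-GAPDH_5 had a level of 6.98 ± 0.42 (SD, n = 3) in ND, 7.19 ± 0.18 (SD, n = 3) in HF and 6.88 ± 0.12 (SD, n = 3) in HE. Two-sided exact permutation tests gave p = 0.90 for Mouse-PGK1_3 and p = 0.50 for Mouse-GAPDH_5 between HF and ND. Between HE and HF the exact permutation p was 0.70 for Mouse-PGK1_3 and 0.10 for Mouse-GAPDH_5, and 3 arrays against 3 cannot go below 0.10. A sign of RNA quality, the level of the 3' probe Mouse-PGK1_3 minus that of the 5' probe Mouse-PGK1_5, was 2.40 ± 0.12 (SD, n = 3) in ND, 2.30 ± 0.13 (SD, n = 3) in HF and 2.08 ± 0.12 (SD, n = 3) in HE. The ND and HE arrays did not overlap in it (exact permutation p = 0.10). For Mouse-GAPDH_3 minus Mouse-GAPDH_5 the difference between HE and ND was 0.017 (exact permutation p = 0.90), and that between HF and ND -0.182 (exact permutation p = 0.10). The Pgk1 measure, chosen after its values were seen, had a correlation of -0.717 with the first principal component over the 9 arrays (exact permutation p = 0.029, adjusted 0.12 over 4 relations). It was -0.960 on slide 1, -0.887 on slide 2 and -0.876 over both with slide means removed (exact permutation p = 0.0087, adjusted 0.035). The Gapdh measure had a correlation of 0.243 with that component over the 9 arrays (exact permutation p = 0.53). On slide 1 it was -0.304, on slide 2 0.778 and over both 0.614 (exact permutation p = 0.25).

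The first comparison asked what the high fat diet alone shifted in the aorta. Probe A_55_P2158314 (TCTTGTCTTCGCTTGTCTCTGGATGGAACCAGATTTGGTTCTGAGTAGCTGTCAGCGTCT) was higher in HF by 1.36 ± 0.16 (SE, n = 3 per group) on the log2 scale, with adjusted p = 0.179. Its level was 0.74 ± 0.07 (SD, n = 3) in HF and -0.61 ± 0.26 (SD, n = 3) in ND. Probe A_55_P2068459 (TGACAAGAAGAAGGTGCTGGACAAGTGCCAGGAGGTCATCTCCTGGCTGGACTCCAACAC) was higher in HF by 1.21 ± 0.15 (SE), from a level of 2.44 ± 0.14 (SD, n = 3) in ND to 3.65 ± 0.23 (SD, n = 3) in HF. Probe mmu_18159_PI428960544 (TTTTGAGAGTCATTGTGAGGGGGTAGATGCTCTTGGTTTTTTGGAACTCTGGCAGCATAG) was well above background on 3 of 3 ND arrays and on 0 of 3 HF arrays. Against the lowest signal among probes well above background, it was 2.45-fold lower in HF in the processed signal. That fold is no firm lower bound, since the probe was also not well above background at a level of -2.19 on HE replicate 1. The normexp background correction with an offset of 50, which shrinks dim signals, gave a log2 difference of -0.37. The 2.45-fold value sets the ND mean against, on each HF array, the higher of the probe's own signal and the lowest signal among probes well above background. Probe mmu_28906_PI428960544 (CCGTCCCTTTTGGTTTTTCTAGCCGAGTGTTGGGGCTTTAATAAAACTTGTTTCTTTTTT) had a log2 difference of -1.13 ± 0.14 (SE), with a level of -0.79 ± 0.09 (SD, n = 3) in ND and -1.93 ± 0.02 (SD, n = 3) in HF. After normexp the log2 difference of mmu_28906_PI428960544 was -0.407. The probes named are the 2 per direction with the smallest unadjusted p among those that differed by at least 1 on the log2 scale. None of the 4 passed, each with adjusted p = 0.179. The normexp background correction put A_55_P2158314 and A_55_P2068459 past the threshold, and over the settings other than spike-in scaling and the fits within a slide their adjusted p ran from 0.046 to 0.62 and from 0.020 to 0.62.

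In limma's moderated test over the 43948 probes, 0 probes differed between HF and ND at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 4311 probes, 1973 higher and 2338 lower in HF, where 2197 would be expected by chance. Probes that vary together widen the spread around that number. Of the 4311 probes, 106 were at least 2-fold higher and 202 at least 2-fold lower. This split depended on single arrays, with 297 and 205 without ND replicate 1 and 205 and 567 without HF replicate 1. The split turned with the scaling, since setting each array to its median gave 3488 higher and 1340 lower. The HF and ND arrays did not overlap for 16.3% of the probes, where chance gives 10%.

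The split of the probes differed between name series. The series of names decides here only how probes are grouped, because the files do not say which series target messenger or long non-coding RNA. Among 4502 tested probes named A_51_P, 336 were higher and 92 lower in HF at an unadjusted p under 0.05, with a median log2 difference of 0.089. Among 14329 tested probes named mmu, 566 were higher and 1014 lower, with a median log2 difference of -0.041. The median level of the A_51_P and A_52_P probes minus that of the mmu probes was 0.59 ± 0.13 (SD, n = 3) in ND and 0.72 ± 0.08 (SD, n = 3) in HF, and the ranges of the arrays overlapped (exact permutation p = 0.30). HF replicate 1 on slide 1 had 0.636, inside the ND range of 0.451 to 0.694, and the HF arrays of slide 2 had 0.762 and 0.771. This difference within an array does not depend on the scaling.

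Slide and diet overlapped in this comparison. With slide as a block, 25 probes were lower and 0 higher in HF at an adjusted p under 0.05, and 2683 passed an unadjusted p of 0.05, 607 higher and 2076 lower. That estimate rests on the 1 HF array of slide 1 against the 3 ND arrays, and within slide 1 alone 0 probes passed and 2374 had an unadjusted p under 0.05. The differences within slide 1 were 1.37 for A_55_P2158314, 1.31 for A_55_P2068459 and -1.15 for mmu_28906_PI428960544, while mmu_18159_PI428960544 was not well above background on that HF array.

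**Figure D2:**
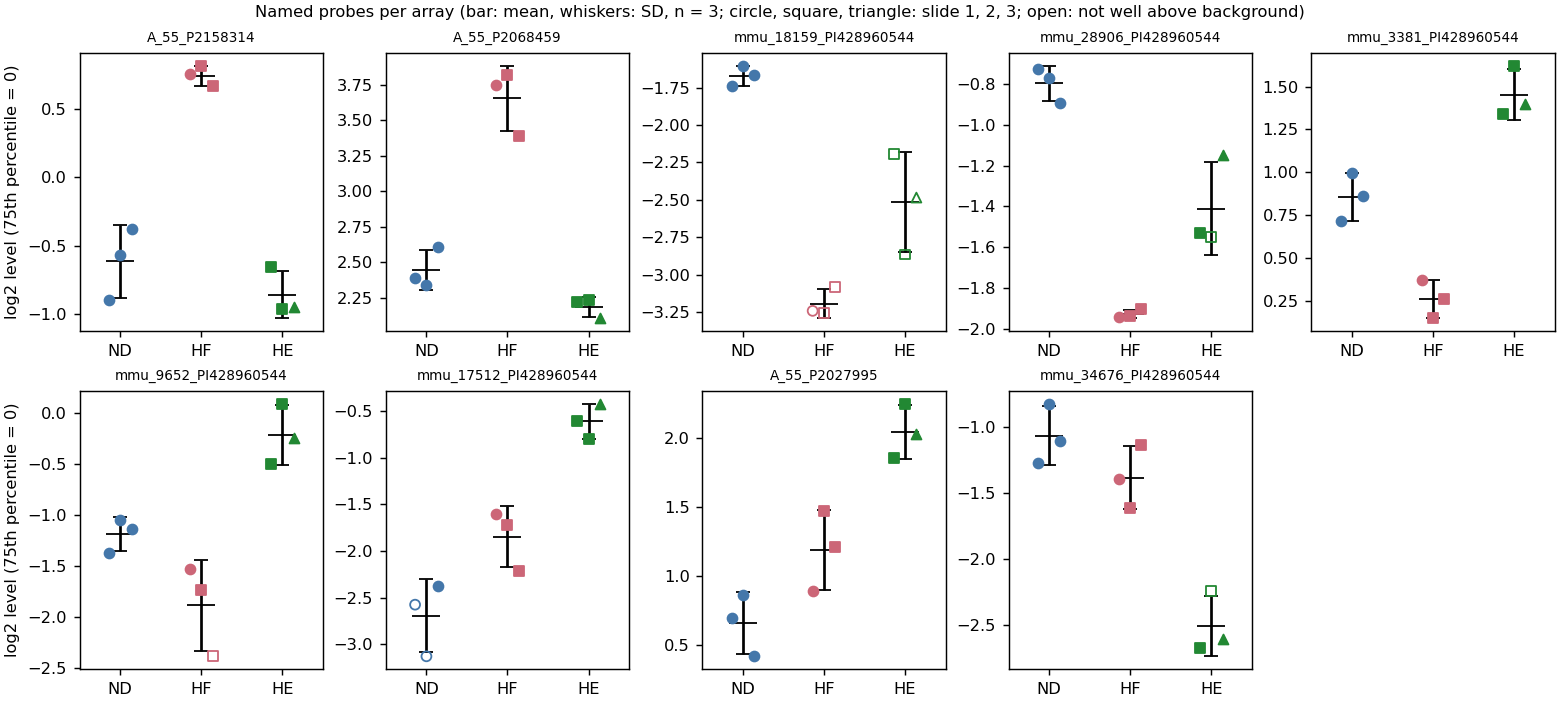
Each panel shows 1 named probe, with the log2 level relative to the array's 75th percentile on the y axis and the 3 groups on the x axis. Points are arrays (symbols give the slide, open points are not well above background), bars are means and whiskers are SD (n = 3). A_55_P2158314 and A_55_P2068459 are higher in all 3 HF arrays than in the other 6 arrays.

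The second comparison asked what exercise changed under the high fat diet. The same pair of probes that were higher in HF than in ND were lower in HE than in HF. A_55_P2158314 differed by -1.60 ± 0.16 (SE, n = 3 per group) and A_55_P2068459 by -1.47 ± 0.15 (SE) on the log2 scale, each with adjusted p = 0.071. Both comparisons use the same HF arrays, so an array error in HF would also produce such a pair of opposite differences. Their levels in HE were -0.86 ± 0.17 (SD, n = 3) and 2.18 ± 0.07 (SD, n = 3). Probe mmu_3381_PI428960544 (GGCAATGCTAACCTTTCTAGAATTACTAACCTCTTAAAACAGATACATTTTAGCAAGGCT) was higher in HE by 1.19 ± 0.14 (SE), with a level of 1.45 ± 0.15 (SD, n = 3) against 0.26 ± 0.11 (SD, n = 3) in HF and adjusted p = 0.128. Probe mmu_9652_PI428960544 (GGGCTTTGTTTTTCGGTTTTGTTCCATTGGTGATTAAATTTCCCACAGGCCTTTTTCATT) was higher in HE by 1.67 ± 0.24 (SE), with adjusted p = 0.221, and was well above background on 2 of 3 HF arrays. After normexp the log2 difference of mmu_9652_PI428960544 was 0.741. Within slide 2, with 2 arrays per group, the differences were -1.55, -1.38, 1.28 and 1.86 for these 4 probes in the order given.

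In limma's test 0 probes differed between HE and HF at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 5465 probes, 2749 higher and 2716 lower in HE, against 2197 by chance. A 2-fold difference was reached by 108 of the higher and 105 of the lower probes, but by 280 and 130 without HF replicate 2, 226 and 120 without HF replicate 1, 178 and 98 without HF replicate 3, 198 and 236 without HE replicate 1 and 153 and 300 without HE replicate 3. With each array set to its median, which falls among dim probes, the split was 1440 higher and 4435 lower. The arrays of the 2 groups did not overlap for 21.6% of the probes, where chance gives 10%. A_55_P2158314, A_55_P2068459 and mmu_3381_PI428960544 were the 3 probes past the adjusted threshold with only probes detected on all 9 arrays, with a trended and robust prior and with array weights, and all 3 were among the 12 called after the normexp background correction. Over the settings other than spike-in scaling and the fits within a slide their adjusted p ran from 0.013 to 0.51, from 0.0029 to 0.51 and from 0.019 to 0.59.

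The splits by name series were opposite here, as the HF arrays that both comparisons share would also give without an effect. Among the A_51_P probes 134 were higher and 480 lower in HE than in HF at an unadjusted p under 0.05, and among the mmu probes 1218 were higher and 537 lower. The median level of the A_51_P and A_52_P probes minus that of the mmu probes was 0.57 ± 0.06 (SD, n = 3) in HE, below each of the HF arrays (exact permutation p = 0.10, the smallest the design allows). Between HE and ND, which do not share the HF arrays, it differed by -0.024 (exact permutation p = 0.80). With slide as a block 0 probes passed the adjusted threshold and 5112 an unadjusted p of 0.05, and within slide 2 the numbers were 0 and 5194.

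The E1A spike-in probes, which measure RNA added from outside at labelling, were higher in HE. The mean level of the 4 bright E1A probes was 3.77 ± 0.04 (SD, n = 3) in HE, 3.37 ± 0.01 (SD, n = 3) in HF and 3.28 ± 0.16 (SD, n = 3) in ND. The slope of the spike-in fit, as reported by Feature Extraction, was 0.981 on HE replicate 2 and 0.778 to 0.841 on the other arrays. Scaling the arrays to these probes in place of the 75th percentile, a setting chosen after seeing the data, gave a median log2 difference over probes of -0.40 between HE and HF and of -0.51 between HE and ND.

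The third comparison set trained mice on high fat diet against mice on normal diet. Probe mmu_17512_PI428960544 (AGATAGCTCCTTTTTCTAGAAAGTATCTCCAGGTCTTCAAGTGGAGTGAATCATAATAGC) was well above background on 3 of 3 HE arrays and on only 1 of 3 ND arrays. Its log2 difference of 2.09 ± 0.23 (SE, n = 3 per group) is therefore partly one from background, and it was 0.74 after normexp. Probe A_55_P2027995 (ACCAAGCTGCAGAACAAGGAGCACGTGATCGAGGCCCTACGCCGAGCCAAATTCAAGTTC) had a level of 2.04 ± 0.20 (SD, n = 3) in HE, 1.19 ± 0.29 (SD, n = 3) in HF and 0.66 ± 0.22 (SD, n = 3) in ND, a log2 difference between HE and ND of 1.39 ± 0.19 (SE). Probe mmu_34676_PI428960544 (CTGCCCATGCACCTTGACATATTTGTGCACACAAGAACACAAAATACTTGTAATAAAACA) had a level of -2.51 ± 0.23 (SD, n = 3) in HE and -1.07 ± 0.23 (SD, n = 3) in ND, a log2 difference of -1.44 ± 0.18 (SE). For this probe 2 of 3 HE arrays were well above background, and the log2 difference was -0.312 after normexp. None of the 3 probes passed, each with adjusted p = 0.156. Among probes that differed by at least 1 on the log2 scale, the one lower in HE with the smallest unadjusted p was left out and not replaced.

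In limma's test 0 probes differed between HE and ND at an adjusted p under 0.05. This comparison had 6468 probes at an unadjusted p under 0.05, 3438 higher and 3030 lower in HE, with 277 at least 2-fold higher and 298 at least 2-fold lower. That split turned with 1 array, to 432 and 227 without ND replicate 1 and to 450 and 826 without HE replicate 3. The arrays did not overlap for 20.5% of the probes, where chance gives 10%. The 3' minus 5' difference of Pgk1 differed by -0.315 between these groups. No slide held both groups, so that the slide block compares them only through the HF arrays. It left 0 probes past the adjusted threshold and 3420 at an unadjusted p under 0.05, 1329 higher and 2091 lower, with a log2 difference of 0.94 ± 0.33 (SE) for A_55_P2027995. Without HE replicate 2, the array with the fewest probes above background, 4292 probes had an unadjusted p under 0.05.

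**Figure D3:**
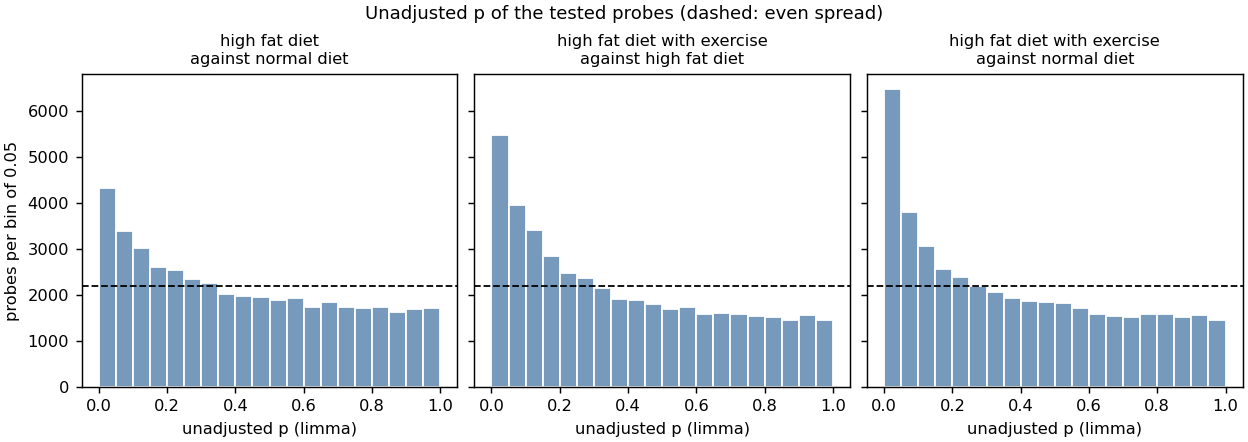
The histograms count the 43948 tested probes (y axis) by limma's unadjusted p (x axis, bins of 0.05) in each comparison. The dashed line is an even spread, 2197 probes per bin, and the first bins hold 4311, 5465 and 6468 probes.

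The design also asks if exercise moves probes back that the diet had moved. Across the 43948 probes, which are not independent replicates, the log2 difference between HF and ND and that between HE and HF had a Pearson correlation of -0.36. Both use the HF arrays. In 100 simulations of unchanged groups the mean was -0.50 with a range of -0.5152 to -0.4787, below the observed value. The simulated groups hold no slide effect or other variation that probes share, so their range cannot tell if the groups changed. Leaving out 1 array moved the observed correlation from -0.52 to -0.19. The value of unchanged groups also shifts with the arrays left out, and it was not simulated for these. The covariance was -0.0343 and the simulated one -0.0354, with a range of -0.0372 to -0.0334 that holds the observed value. With slide as a block the diet difference comes from slide 1 and the exercise difference from slide 2, so that they share no HF array. The correlation was then -0.01, and 0 is the value without any effect.

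Of the probes at an unadjusted p under 0.05, 478 were higher in HF than in ND and lower in HE than in HF, and 532 were lower and then higher. As shares of the probes that differed between HF and ND, these are 24.2% and 22.8%, and simulated unchanged groups that share the HF arrays gave 23.4% and 23.3%, so the shared arrays alone give as large a share. Another 72 probes (3.6%) were higher in both steps and 6 (0.3%) were lower in both, where the simulated groups gave 0.5% and 0.3%. The simulated groups hold no slide effect, while the slides run from ND over HF to HE, so that a difference between slides would also add probes that differ in the same direction in both steps. The difference between HF and ND and that between HE and ND, which share the ND arrays, had a correlation of 0.55 against a simulated 0.50 (range 0.4816 to 0.5198), and a covariance of 0.0600 against 0.0353 (range 0.0336 to 0.0372). Both observed values lie above the simulated ranges.

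**Figure D4:**
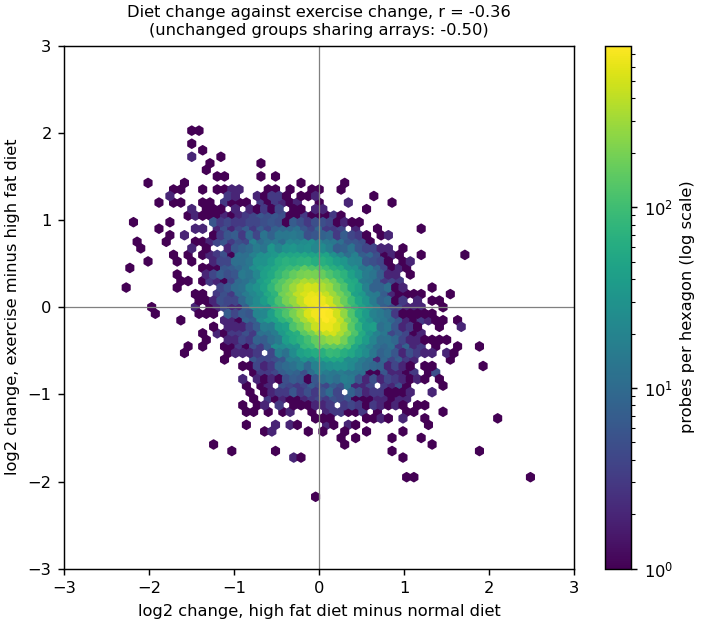
Hexagons count tested probes by their log2 difference between HF and ND (x axis) and between HE and HF (y axis), with colour on a log scale, and 2 probes lie outside the axes. The cloud slopes down with r = -0.36, and unchanged groups that share the HF arrays give -0.50.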

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

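The tests of the E1A probes, the choice of the 4 bright ones, the tests on the place of HF replicate 1 and on RNA quality and the restriction of second probes to those with 1 partner were chosen after the results had been seen. The E1A spike-in probes are controls that no comparison uses, and they stood out because all 3 HE arrays lay above all 6 other arrays, with a mean log2 difference of 0.443. The difference was 0.398 against HF and 0.488 against ND (exact permutation p = 0.10 for each, the smallest that 3 arrays against 3 allow). The tables argue against the slide, because on slide 2 alone HE replicates 1 and 2 exceeded HF replicates 2 and 3 by 0.414, with an SD of 0.111 over the 6 other arrays. The 4 bright probes shifted by nearly the same amount, with an SD between probes of 0.026, but any offset of a whole array would give this, so that a different ratio of spike-in to labelled RNA stays open. Dimmer HE arrays stay open too, since before scaling the HE mean was still 0.259 higher but the arrays of the groups overlapped, and a lower share of messenger RNA in the trained aorta is a biological explanation that was not tested.

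The arrays of slide 1 and slide 2 lay apart on the first principal component. The share of probes detected does not account for it, as the gap between the slides was 36.9 before and 34.03 after regression on that share, but RNA quality stays open, as 12.88 was left after regression on the 3' minus 5' difference of Pgk1 and 39.2 after regression on that of Gapdh. A slide effect may contribute: HF replicate 1 minus the other HF arrays and ND minus HE replicates 1 and 2 share no array, are both differences of slide 1 and slide 2, and correlated at 0.276 across probes, between the bounds of 0.1 and 0.3 set for no effect and for an effect. HF replicate 1 lay nearer to ND than to the other HF arrays by 25.09 units. HE replicate 3, on slide 3, lay at -13.0, below HF replicates 2 and 3 (16.5 and 15.5) and HE replicates 1 and 2 (31.1 and 72.3). Neither place follows the groups, but each is that of 1 array, which cannot exclude that diet or training alone orders the arrays. Slide and diet are separated only through HF replicate 1, since it is the 1 HF array of slide 1 and slide 2 held no ND array.

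More probes than chance had an unadjusted p under 0.05 in each comparison. Noise of single spots is not the cause, as shown by probes that share at least 30 bases with exactly 1 other tested probe (1309 pairs). The second probe differed in the same direction for 89.0%, 95.2% and 86.8% of the probes past that level in HF against ND, HE against HF and HE against ND, where shuffled pairs gave 45.1%, 45.4% and 46.2%. Over all 3014 pairs, many of them in repeat families, the shares were 94.9%, 95.8% and 88.3%, with a probe counted once for each partner. The real split of the 6 arrays gave the highest count in each comparison, 4311 against 4198 for the highest other split, 5465 against 3694 and 6468 against 4326, but 10 splits, of which 1 is the real one, are too few for a share under 0.05. The other split with 4198 set ND replicate 1 with HF replicates 2 and 3 against ND replicates 2 and 3 with HF replicate 1. It thus partly follows the slides, and the counts with slide as a block were 2683, 5112 and 3420. At the adjusted threshold the real split of HE against HF gave 0 probes. The split of HF replicates 1 and 2 with HE replicate 3 against HF replicate 3 with HE replicates 1 and 2 gave 5.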

How the results depend on the processing

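The scaling to spike-ins and the fits within a slide were chosen after seeing the data; the other settings were set before the data were examined. Of HF against ND, HE against HF and HE against ND, 0 probes passed the adjusted threshold with quantile normalization, the array median, the 75th percentile of detected probes, no filter, only the groups compared, the authors' value table and each array left out in turn. The normexp background correction called 4, 12 and 1 probes. In HE against HF, 3 probes were called with probes detected on all arrays, 3 with the trended and robust prior and 3 with array weights. With slide as a block 25 were called in HF against ND, where 1 HF array carries the estimate. At an unadjusted p under 0.05 with at least a 2-fold difference there were 308, 213 and 575, with 20, 21 and 69 after normexp, 65, 59 and 224 with probes detected on all arrays, 723, 480 and 1497 with slide as a block, 774, 571 and 1053 with no filter and, leaving out 1 array, 257 to 772, 203 to 453 and 384 to 1276. Spike-in scaling called 9590 in HE against HF and 19053 in HE against ND, nearly all lower, because it moves every probe by the spike-in difference, and it had 18344 and 24907 at an unadjusted p under 0.05. That count was 2683 in HF against ND and 3420 in HE against ND with slide as a block, and 2374 within slide 1. Leaving out 1 array gave 2733 (without HF replicate 2) to 6029 (without HF replicate 1) in HF against ND, 3387 (without HF replicate 3) to 5783 in HE against HF, and 4292 (without HE replicate 2) to 8018 in HE against ND; it was also 2872 without ND replicate 2 and 2762 without HF replicate 3 in HF against ND. The share of those probes that were higher was 45.8%, 50.3% and 53.2%. It was 72.2%, 24.5% and 53.1% with the array median, which falls among dim probes. With slide as a block it was 22.6%, 53.0% and 38.9%, and with spike-in scaling 18.3%, 0.5% and 0.7%. In HE against HF it was 39.0% with normexp, 61.7% without HF replicate 3 and 65.7% with no filter. The correlation of diet and exercise differences was -0.013 with slide as a block, and leaving out 1 array gave -0.52 (without HF replicate 1) to -0.19 (without HE replicate 3). The cause of the other changes was not tested. Each of the 245 values of named probes over all settings kept its direction. These probes were picked for a large difference on the same arrays, so a kept direction is no support for them. Normexp shrank the dim ones, to -0.374 for mmu_18159_PI428960544, -0.407 for mmu_28906_PI428960544, -0.312 for mmu_34676_PI428960544, 0.745 for mmu_17512_PI428960544 and 0.741 for mmu_9652_PI428960544. It also shrank A_55_P2158314, to 0.889 in HF against ND and to -0.967 in HE against HF.

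With the replicate number as a replicate block, 0 probes passed in each comparison, and 3360, 4494 and 5490 had an unadjusted p under 0.05. Deviations from the group means of arrays with the same number correlated at -0.25 to 0.137, over 0.1 in 1 of 9 pairs, and 0 of the 9 arrays correlated best with its own number, so that the arrays share only a number.

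Not run, because the files pair no probe with a gene, were the mean of the probes of a gene, the highest probe of a gene, the covariates for adipocyte and skeletal muscle lists, the counts of long non-coding RNAs, the check of sex-linked genes and the shifts of gene lists with camera, an estimated correlation or fry. Signal over background limits the named probes mmu_18159_PI428960544 and mmu_17512_PI428960544 most, since they were above background on 0 of 3 HF arrays and 1 of 3 ND arrays.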

Other observations

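The sequence families, the relations of Pgk1, the restriction of opposite strands to probes with 1 partner and the use of the highest of the 3 correlations there were chosen after the results had been seen. Of the tested probes that share at least 30 bases on the same strand, the 4 largest families were examined, and those of 31 and 21 probes differed little between HF and ND (median log2 differences of -0.026 and -0.037, exact permutation p = 0.90 for each). Another is a family of 32 probes that all carry a run of GT repeats. All 32 had a lower level in HF than in ND, with a median log2 difference of -0.374 and no single adjusted p below 0.403. The family's median level was 7.66 ± 0.06 (SD, n = 3) in ND, 7.28 ± 0.08 (SD, n = 3) in HF and 7.501 ± 0.127 (SD, n = 3) in HE, and the ND and HF arrays did not overlap (exact permutation p = 0.10, the smallest the design allows). All 32 were also lower in HE than in ND, with a median log2 difference of -0.185, and those arrays did not overlap (exact permutation p = 0.10). The family's difference of HE and ND was -0.158, and ran from -0.063 in the authors' value table to -0.645 with spike-in scaling. No slide held both groups, so slide and group cannot be told apart there. Between HE and HF the exact permutation p was 0.20. On slide 1 alone the log2 difference of HF replicate 1 and ND was -0.287. The difference of HF and ND stayed negative with each scaling tried, from -0.258 in the authors' value table to -0.465 with spike-in scaling. The difference of HE and HF was 0.218 and turned to -0.180 with spike-in scaling. Probes that share a repeat can bind many transcripts, so these are not 32 independent measurements.

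A second family of 43 probes, 95.3% of which carry a run of AAG, AGG or AGA repeats, was higher in HE than in HF for 43 of 43 probes. Its median log2 difference was 0.387, with a family level of 1.23 ± 0.23 (SD, n = 3) in HE and 0.85 ± 0.24 (SD, n = 3) in HF (exact permutation p = 0.20). With spike-in scaling the difference was -0.020. On slide 2 it was 0.572. Between HF and ND 41 of the 43 probes were lower in HF, with a median log2 difference of -0.318 (exact permutation p = 0.30 for the family level). On slide 1 alone the log2 difference of HF replicate 1 and ND was -0.012. Between HE and ND 23 probes were higher and 20 lower in HE, with a median log2 difference of 0.078 (exact permutation p = 0.60 for the family level).

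The level of Pgk1 followed the second principal component, which holds 19.1% of the variance. Over the 9 arrays Mouse-PGK1_3 and that component had r = 0.883 (exact permutation p = 0.0017, adjusted 0.0034 over 4 relations) and Spearman's rho of 0.80 (exact permutation p = 0.014). Without ND replicates 1 and 2, the arrays farthest from the median of Mouse-PGK1_3, r was 0.823 (exact permutation p = 0.025, 7 arrays). Mouse-PGK1_3 and Mouse-GAPDH_5 had r = 0.907 (exact permutation p = 0.0010, adjusted 0.0034), rho of 0.767 (exact permutation p = 0.021) and r = 0.777 without those arrays (exact permutation p = 0.043). With the first component r was -0.141 (exact permutation p = 0.72), and with the difference between name series it was 0.558 (exact permutation p = 0.11). On slide 1 (4 arrays) and slide 2 (4 arrays) the second component had r = 0.975 and 0.830, and over both after removing the slide means 0.912 (exact permutation p = 0.017, within slides). Mouse-GAPDH_5 had 0.990, 0.867 and 0.936 (exact permutation p = 0.0087), and the difference between name series 0.899, 0.480 and 0.738 (exact permutation p = 0.075). The first component had -0.291, -0.631 and -0.365 (exact permutation p = 0.28), and slide 3 holds 1 array. ND replicates 1 and 2 had Mouse-PGK1_3 levels of 4.14 and 2.57, the highest and lowest of the 9 arrays.

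A hypothesis was that the 2 strands of a locus change together. The array holds 2378 pairs of probes that match opposite strands over at least 30 bases. Both probes of a pair were tested in 36.9% of the pairs, where 31.3% would be with independent detection. Among the 477 tested pairs without further partners, the correlation across pairs of the log2 differences was 0.069 in HF against ND, 0.169 in HE against HF and 0.018 in HE against ND. Pairs on the same strand had 0.537, 0.574 and 0.545. Over all 878 tested pairs, repeat families included, the values for opposite strands were -0.138, 0.086 and 0.017. Over all pairs a probe past an unadjusted p of 0.05 was counted once for each partner, so few repeat probes can set a share. Of 271 such counts in HF against ND only 20.7% went the same way as the partner, where shuffled pairs gave 52.8%. Pairs of probes with several partners thus mostly went opposite ways there. With 1 partner the share was 54.1%. In HE against HF the shares went the other way, 65.6% over all pairs and 69.2% with 1 partner, where shuffled pairs gave 53.4% and 54.1%. No value reaches the 0.3 set in advance for strands that change together, and 0.169 lies above the 0.1 set for no relation, so that a weak relation stays open.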
